A study of Rattus norvegicus with 8 samples.

How the data were processed

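RNA of purified rat RGCs was amplified in successive rounds and labelled with Cy5, and a commercial rat reference RNA was labelled with Cy3 in the same way, per the labels' protocols. There were 4 control and 4 COH samples on 8 Agilent rat oligonucleotide arrays, with the same dye orientation on every array, so dye bias cannot be separated from the ratio to the reference. It cancels in the COH against control difference as far as it is equal on all arrays. According to the design text, RNA came from both eyes of the same animals, pooled into 4 independent groups. The p-values therefore measure the spread between pools, and the number of animals per pool is not given in the sources used here.

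The deposited values are log2 ratios of RGC over reference RNA per spot, normalised by the authors with Lowess over the whole array and locally and restricted to spots that passed Agilent quality criteria, per the design text. The software and its version are not given in the sources used here. The log base was read from the values: each array holds frequent identical values, and pairs of these lie exactly 2 apart (tolerance 2e-05), as whole-number signal ratios of 2 to 1 and 1 to 2 do on a log2 scale. The direction, on which every sign depends, was taken from the dyes in the labels and the ratios named in the design text; the value table itself does not state it. Medians per array were 0.00 (control 1), -0.05 (COH 1), -0.004 (control 2), -0.02 (COH 2), 0.13 (control 3), -0.06 (COH 3), -0.01 (control 4) and 0.00 (COH 4). Signal intensities and background flags were not used here. As a stand-in, a value that at least 3 spots of an array shared exactly was taken as a sign of low signal. Such values made up 50.9% to 59.6% of an array, and 9767 spots had distinct values (shared by at most 2 spots) on all 8 arrays.

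Of the 45220 spots, 25353 had 1 gene symbol, 48 had several and 19819 had none in the probe annotation table. Symbols were updated through the gene identifier, which 25306 of the spots with 1 symbol had in the reference table of rat genes. Spots with a value on all 8 arrays were kept and spots of 1 symbol were averaged per gene. The rest were tested under their own probe number. Of 2438 genes with several spots, 1421 had spot means more than 1 log2 unit apart, so that different probes of a gene often disagreed in level.

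The test was limma (version 3.58.1, R 4.3.3) with lmFit and eBayes on all 8 arrays, two-sided, with the replicate number as a block and Benjamini-Hochberg adjustment over 18595 items at 0.05. The pairing comes from the design text, which takes ratios within each pooled group of animals, and from the shared numbers 1 to 4 in the sample titles. The deviations from the group means of same-numbered arrays correlated at 0.09, 0.02, 0.06 and 0.03. Those of differently numbered control and COH arrays correlated at -0.19 to 0.09, so the values alone do not establish the pairing. The exact form of the design text's analysis of variance is not given, so its rule (p under 0.05 and at least 1.5-fold) was applied to limma's p. Intervals are 95% intervals from the moderated fit, and those of list means come from the spread of the 4 pairs. Gene lists were tested with camera (preset correlation 0.01), camera with an estimated correlation, and fry. Camera compares the list with all other genes, while fry tests whether its genes move one way. Of 33 lists fixed in advance, 32 had at least 5 measured members; the list of erythrocyte genes had 3 and was not tested.

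The analysis was tested on simulated data. Gene variances were drawn from the fitted prior, whose degrees of freedom were 3.86 in the data and 3.84 on average in 20 simulations. A first version that drew from the raw residual SDs overdispersed the variances and was replaced. For gene lists, COH and control were exchanged within some pairs of the real data and a known shift was added. Camera with the preset correlation called a shift of 0.5 log2 units in the 20 RGC markers in 14 of 14 trials and in the 18 microglia and macrophage markers in 10 of 14. With an estimated correlation it called a shift of 1 in either list in 0 of 14, so that version has little power for short lists.

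Named genes followed a rule fixed before the data were examined: genes past the adjusted threshold with the same direction in 4 of 4 pairs, filled up to 10 per direction with those of smallest unadjusted p, at least 1.5-fold and 4 of 4 pairs. A further 13 markers were always named where measured, which was so for 8; 1 of the 13 is not reported here. Examples within gene lists (Lcn2, Steap4, C4a, C3, Ankrd1, Socs3, Nrtn and Gdnf) were chosen after their values were seen. Alternatives set in advance covered scaling between arrays, the block, array weights, filters on incomplete, extreme or zero values, probe-level tests, other priors, a test of the 4 within-pair ratios, other thresholds, other list tests and each pair left out. Chosen after seeing the data were spots with distinct values, removal of a smooth trend over array position (loess, span 0.1, on feature rows of 85 spots taken from the probe numbers), both together, a fit without the block and the COH 4 array, and genes with at least 5 spots. Figures were drawn with matplotlib 3.10.9.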

Results

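Gene expression was measured in retinal ganglion cells (RGCs), the neurons whose axons form the optic nerve, after purification from rat eyes. Eyes with chronic ocular hypertension (COH), a lasting rise of pressure in the eye used as a model of glaucoma, were compared with the normotensive fellow eyes. There were 4 control and 4 COH samples. Each was hybridised to its own two-colour array against a common rat reference RNA, so that every value is the log2 ratio of RGC RNA over reference RNA. Between 32101 and 42076 of the 45220 spots of an array carried a value, and 22856 spots carried one on all 8 arrays. They gave 18595 items for testing, made up of 9792 named genes and 8803 unnamed probes. The median standard error of a COH against control difference was 0.42 on the log2 scale. In settings chosen after seeing the data, it was 0.37 with the position trend removed and 0.32 for the 8278 items with distinct values. The number of arrays limits the precision but need not be the only limit.

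In control cells, the lists of synaptic and receptor genes had medians above the reference RNA and the cell cycle list one below it. Of 19 measured synaptic vesicle and presynaptic genes, 9 were above the reference on all 4 control arrays and 1 was below, with a median log2 ratio of 0.60. Of 30 glutamate and GABA receptor genes, 18 were above and 2 below (median 0.78). Of 38 axonal transport and microtubule genes, 8 were above and 15 below (median -0.16). Of 33 cell cycle genes, 26 were below on all 4 control arrays and 4 above (median -1.34). The median over all named genes was -0.41. Gap43, a growth-cone protein of neurons, had a log2 ratio of 1.72 ± 0.53 (SD, n = 4) in control cells, as the mean of its 10 probes. These probes disagreed in level, with means over all 8 arrays from 0.87 to 2.36. The light neurofilament Nefl was at 0.41 ± 0.89 and the medium neurofilament Nefm at 0.71 ± 0.42 (SD, n = 4). The spot of Nefl shared its exact value with other spots on 8 of 8 arrays, as low signals do. A ratio depends on the reference as much as on the cells, and the dyes were not swapped, so these levels carry no test. A spot with distinct values was present for 9 of the 19 synaptic and 10 of the 30 receptor genes. Genes of other tissues, described below, had a higher median (1.16), so a ratio above 0 may not show expression in RGCs.

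Markers of other retinal cells were measured in the same way in the control samples. The 20 measured RGC markers had a median log2 ratio of 0.35, with 6 above and 2 below the reference on all 4 control arrays. Photoreceptor markers had a median of 1.10 over 12 genes and bipolar cell markers one of 1.19 over 9 genes. Muller glia markers lay lower, at a median of -0.64 over 14 genes, as did the list of astrocyte and gliosis genes at -1.12 over 18 genes. Microglia and macrophage markers had a median of -0.29 over 18 genes, of which 7 were above and 9 below the reference on all 4 control arrays. A list of 32 measured genes of pancreas, testis, muscle and other tissues, drawn up after the data had been examined, had a median of 1.16, with 17 above the reference on all 4 control arrays and 9 with a mean below 0.

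**Figure D1:**
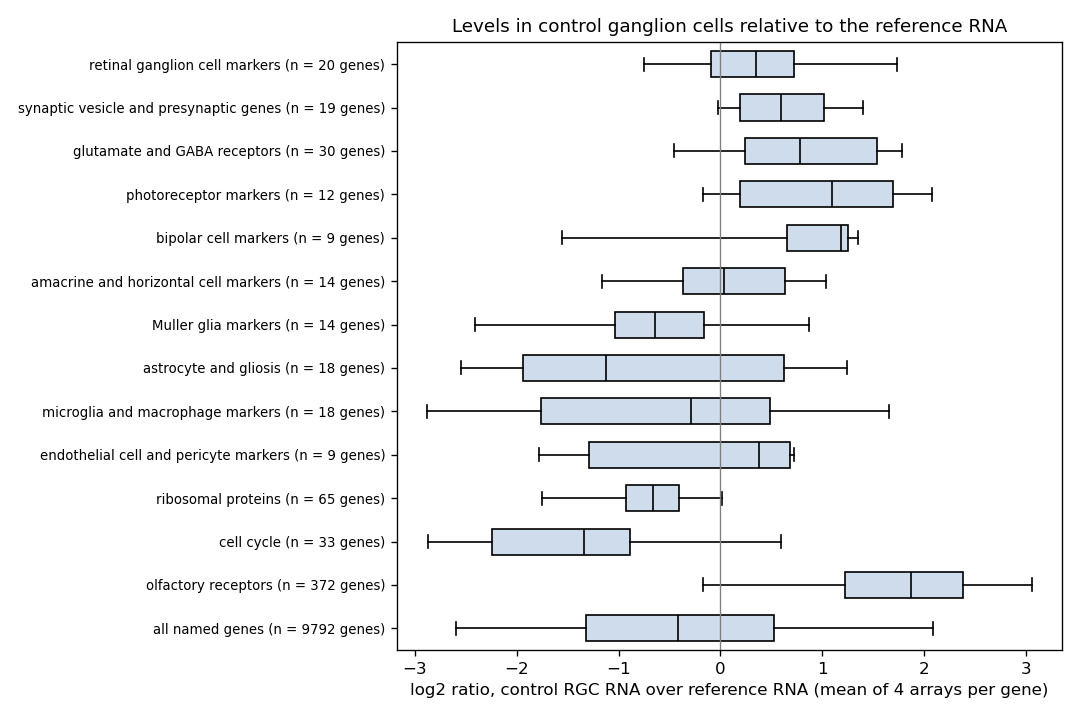
Log2 ratio of control RGC RNA over reference RNA (horizontal axis), with each gene taken as the mean of its 4 control arrays, for 12 of the gene lists, the olfactory receptors and all named genes. Boxes span the quartiles with the median as a line and whiskers reach the 5th and 95th percentiles. The cell cycle list centres on -1.34 and the olfactory receptors on 1.87, against -0.41 for all named genes.

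The main comparison asked which transcripts differ between RGCs of hypertensive eyes and of fellow control eyes. No gene or probe passed the adjusted threshold: limma with the pair as a block gave 0 of 18595 items at an adjusted p under 0.05, with a smallest adjusted p of 0.915, and 880 at an unadjusted p under 0.05. The genes described next are those with the smallest unadjusted p that differed the same way in 4 of 4 pairs. All have an adjusted p of 0.915, so none is past the adjusted threshold.

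Among the genes higher in COH cells, Zfp870, a zinc finger protein, was at 3.21 ± 1.27 in COH and 0.83 ± 1.14 in control cells (log2 ratio, SD, n = 4), a difference of 2.39 ± 0.34 (SE). Tnfsf13, a cytokine of the tumour necrosis factor family, was higher by 2.14 ± 0.34. Map3k4, a kinase at the head of stress-activated kinase cascades, was higher by 1.43 ± 0.32, and Ror2, a receptor tyrosine kinase for Wnt ligands, by 1.78 ± 0.41. Usp30, a deubiquitinase of the mitochondrial outer membrane, was higher by 2.20 ± 0.48, and Ackr3, an atypical chemokine receptor, by 1.70 ± 0.40. The other genes named in this direction were Or4d5 (1.82), Iffo1 (1.68), Itgb1bp2 (1.98) and Zfp217 (1.63). With spots that had at least 3 complete pairs included, Iffo1 was at 0.51 and Zfp217 at 0.94, and without the block and the COH 4 array Itgb1bp2 was at 1.28.

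Among the genes lower in COH cells, Smad4, the common mediator of transforming growth factor beta and bone morphogenetic protein signalling, was at -3.74 ± 0.61 in COH and -1.44 ± 0.79 in control cells (SD, n = 4), a difference of -2.30 ± 0.33 (SE). Cx3cr1, the fractalkine receptor of microglia, was at 0.77 ± 0.95 in COH and 2.82 ± 0.16 in control cells, a difference of -2.05 ± 0.44. St6galnac5, a sialyltransferase that acts on gangliosides, differed by -2.34 ± 0.39. Inpp5e, a phosphoinositide phosphatase of primary cilia, differed by -2.21 ± 0.50 and the vitamin C transporter Slc23a1 by -1.63 ± 0.32. Without pair 2 Inpp5e differed by -2.80. The remaining genes were Or6d13b (-2.39), Or2w6 (-1.95), Derl3 (-1.92), Mpp3 (-1.73) and Dpp4 (-1.43). Of these 20 genes, 4 (Tnfsf13, Map3k4, Ror2 and Zfp217) rest on a spot whose value was distinct on all 8 arrays. These 4 are all higher in COH cells, so no gene named as lower has such a spot. The other 16 had on at least 1 array a value that 3 or more spots shared exactly, as low signals give. For 11 of the 20 genes this was so on 4 or more arrays, and for St6galnac5 and Slc23a1 on 8 of 8. Of the unnamed probes, 28744 and 35737 had the smallest p among those higher in 4 of 4 pairs (2.35 and 2.39), and 7227 and 14406 among those lower (-2.29 and -1.91); none passed the adjusted threshold.

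**Figure D2:**
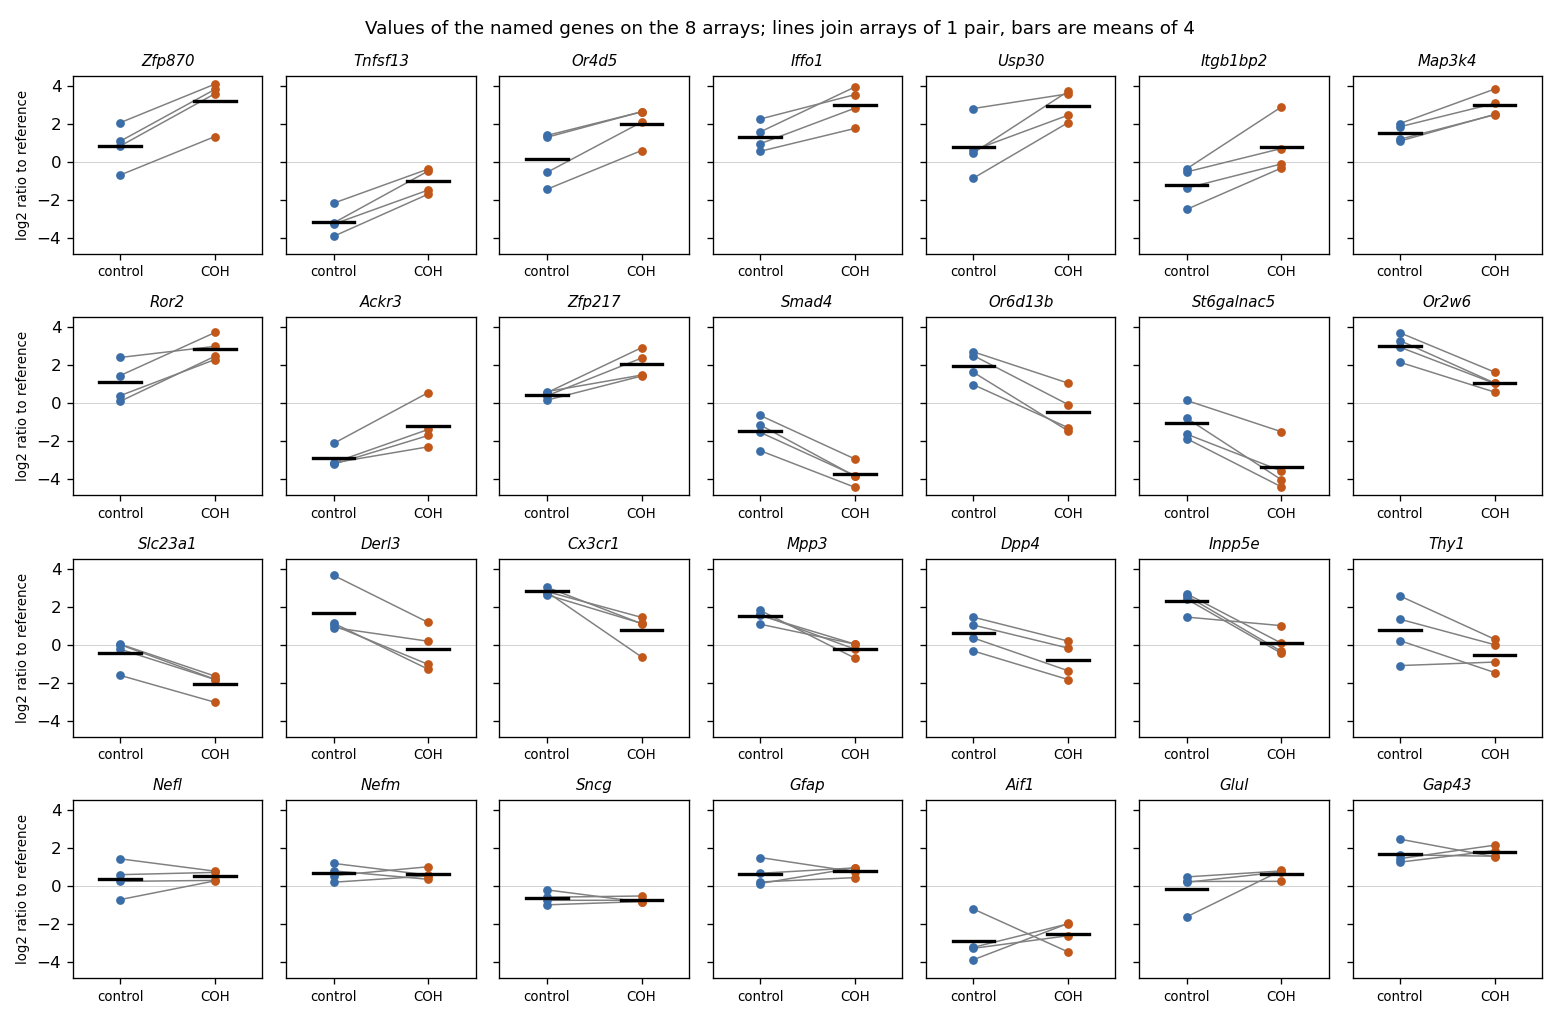
Log2 ratio to the reference RNA (vertical axis) of the 28 named genes in control and COH cells, with a point per array, a grey line joining the arrays of 1 pair and a black bar at the mean of 4 arrays. Cx3cr1 lies between 2.64 and 3.04 in the control samples and between -0.63 and 1.45 in the COH samples.

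The RGC and glial marker genes fixed in advance showed no difference past the adjusted threshold. Thy1, a surface protein used to identify RGCs, was at -0.51 ± 0.81 in COH and 0.77 ± 1.57 in control cells (SD, n = 4). Its difference of -1.28 had a 95% interval from -2.39 to -0.17, and it was lower in 3 of 4 pairs, with a limma adjusted p of 0.915. Nefl differed by 0.13 (95% interval -0.78 to 1.04), Nefm by -0.07 (-0.92 to 0.79), Gap43 by 0.08 (-0.87 to 1.03) and gamma-synuclein, Sncg, by -0.10 (-0.89 to 0.69). Gfap, the intermediate filament of astrocytes and reactive Muller cells, differed by 0.15 (-0.75 to 1.05). Its probes disagreed in level, with means from -0.01 to 1.33. The glutamine synthetase gene Glul, a Muller glia marker, was higher in 4 of 4 pairs by 0.83 (-0.31 to 1.96); without pair 3 the difference was 0.29, and with distinct values and the position trend removed 0.18. Aif1, a marker of microglia, differed by 0.39 (-1.23 to 2.01), and by 1.27 without pair 2. On single arrays all spots of a gene had shared values for Gfap (7 arrays), Aif1 (6) and Thy1 (3). Nefh, Pou4f2 and Pecam1 had no spot with a value on every array, and Pou4f1 was not named in the probe table used here.

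By the rule of the study's design text, an unadjusted p under 0.05 and a change of at least 1.5-fold, 880 items were selected, 477 higher and 403 lower in COH cells. The balance turned over with each array centred on its median (447 and 456), arrays scaled to the same spread (416 and 438) and quantile normalization (423 and 495). It also did so with at least 3 complete pairs (545 and 640), without pair 3 (323 and 467) and with the position trend removed (268 and 523). With distinct values only it was 358 to 73. Of the 880, 413 were named genes and 756 differed the same way in 4 of 4 pairs. At this p threshold 929.75 items would be selected by chance if nothing differed. The fold limit removed none, since the smallest change with such a p was 1.69-fold. Among the selected items 24.8% had a spot with distinct values on all 8 arrays, against 45.5% of the other items tested (Fisher's exact test, two-sided, p = 2.69e-35). Items share the same 8 arrays and are not independent replicates, so this p does not measure a spread between pools. In simulated data with 200 changed genes among 18595, 50.2% of 2-fold and 91.6% of 4-fold changes met this rule, together with 908 unchanged genes on average. The adjusted threshold recovered 0% of the 2-fold and 0.2% of the 8-fold changes, so a count of 0 at 4 pairs does not exclude large changes in this number of genes.

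None of the 32 gene lists tested differed between COH and control cells past the adjusted threshold, by limma's camera with the preset correlation (smallest adjusted p 0.627), with an estimated correlation (0.959) or by fry (0.756). At an unadjusted p under 0.05 camera gave 1 list and fry none. The mean difference of every list had a 95% interval that included 0, and for 31 lists the interval lay within 1 log2 unit of 0. RGC markers differed by 0.05 ± 0.24 (SD of 4 pairs), with 2 of 4 pairs higher, and Thy1 was the member of smallest p. Synaptic vesicle genes differed by -0.02 ± 0.13 and oxidative phosphorylation genes by 0.07 ± 0.10. Glycolysis genes were higher in 4 of 4 pairs, by 0.15 ± 0.13, where 4 pairs allow an exact sign-flip p of no less than 0.125. The cell cycle list had the smallest camera p (0.0468, adjusted 0.627), with a mean difference of 0.26 ± 0.34 and 3 of 4 pairs higher. In 10 lists the mean, the median and the test's direction did not all have the same sign.

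Lists of other cell types were without a call as well. Photoreceptor markers had the highest mean difference, 0.35 ± 0.48 (SD of 4 pairs), and the lens crystallins the lowest, -0.32 ± 0.32. Muller glia markers differed by 0.16 ± 0.32 and astrocyte and gliosis genes by 0.17 ± 0.38. In the latter list Lcn2 had a difference of 0.96 and Steap4 one of 1.002, both with an adjusted p of 0.915. Microglia and macrophage markers differed by -0.03 ± 0.35. Cx3cr1 in that list passed when adjusted over the list alone (limma adjusted p 0.0448, lower in 4 of 4 pairs), as the only such member in any of the 32 lists, and no member of a list passed when adjusted over all genes. Adjusting over a list alone does not allow for the 32 lists looked at, so a single such member can arise by chance. Over 18 other settings the p for Cx3cr1 adjusted over the list alone ranged from 0.00938 to 0.408 and was under 0.05 in 9. Some of these 9 barely alter the fit, such as values of 0 treated as missing (limma adjusted p 0.0448). It lay above that level without pair 1 (0.107), pair 2 (0.0934), pair 3 (0.0835) or pair 4 (0.115). On 4 of 8 arrays at least 3 spots, that of Cx3cr1 included, shared its exact value.

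Lists tied to injury and stress were likewise without a call. Complement genes differed by 0.16 ± 0.45 (SD of 4 pairs). Of the 13 measured, C4a (1.07 ± 0.35, SE) and C3 (0.91 ± 0.34, SE), components of the complement cascade, were higher in 4 of 4 pairs, with an adjusted p of 0.214 over the list alone and 0.915 over all genes. The spot of C4a had a shared value on 8 of 8 arrays. Axon injury genes differed by 0.04 ± 0.38, with Ankrd1 at 1.41 and Socs3, an inhibitor of cytokine signalling, at -1.59 as the members of smallest p. Neurotrophic factors and receptors differed by 0.20 ± 0.27, with the neurotrophic ligands Nrtn at 1.21 and Gdnf at -1.07. Apoptosis genes differed by -0.03 ± 0.48, endoplasmic reticulum stress genes by -0.02 ± 0.29 and antioxidant genes by 0.00 ± 0.27. Ribosomal protein genes differed by -0.22 ± 0.45, with 2 of 4 pairs lower and a median difference of -0.01. With distinct values only, a setting chosen after seeing the data, this list had a camera p of 0.00286 (adjusted p = 0.0828, and adjusted p = 0.982 with an estimated correlation).

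**Figure D3:**
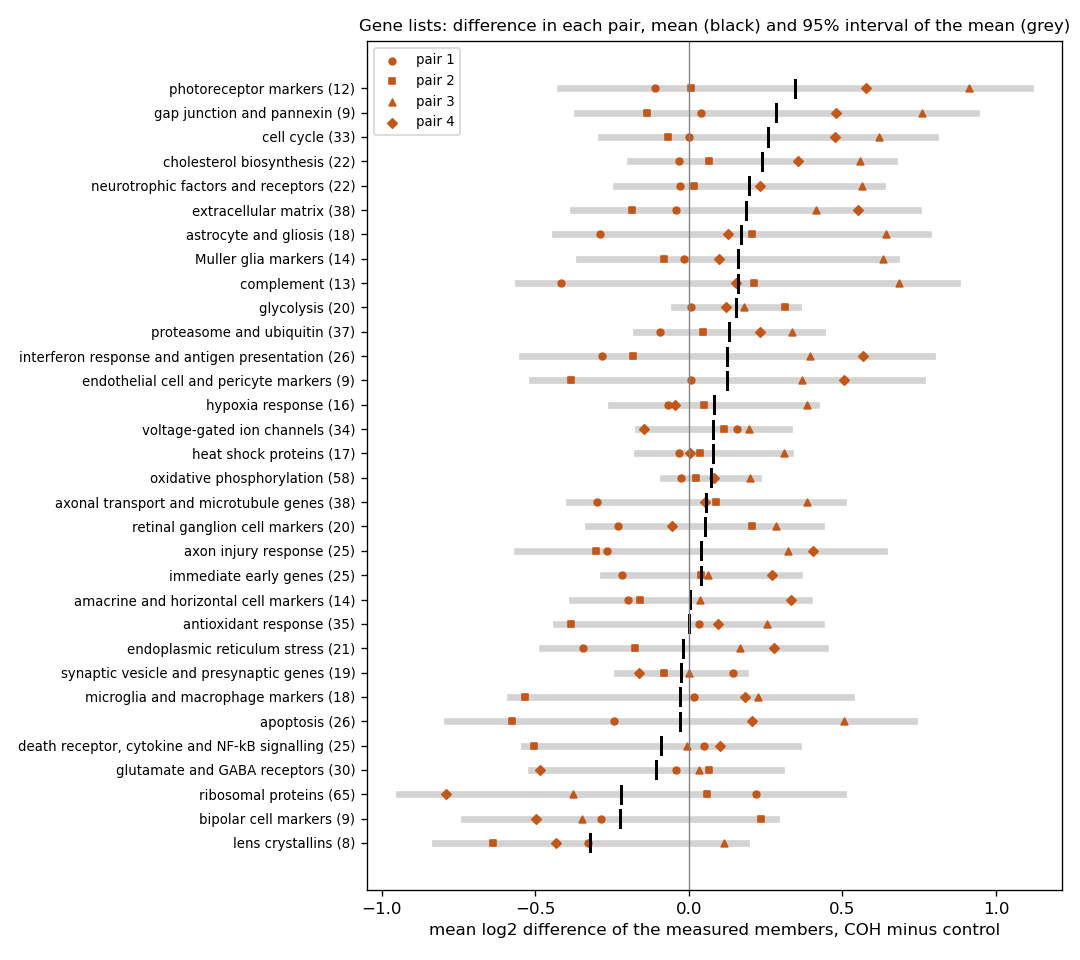
Mean log2 difference, COH minus control, of the measured members of each of the 32 gene lists (horizontal axis), with a symbol per pair, a black tick at the mean of 4 pairs and a grey bar for the 95% interval of that mean from the spread of the pairs. All 32 intervals include 0, and the glycolysis list is the only 1 with all 4 pairs on the same side.

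The arrays differed in precision. Spots of 1 transcript printed at least 5 times had a median SD of 0.78 on the array of COH replicate 4, against 0.31 to 0.57 on the other arrays. On that array the deviation from the median array varied with position, from -0.68 to 0.77 between blocks of feature rows. The range between blocks was 1.44, while the other arrays had ranges from 0.10 to 0.70. Its mean correlation with the other arrays over spots with distinct values was 0.68, compared with 0.77 to 0.84 for the rest (correlations are across spots, which are not independent replicates). Without pair 4 the counts were 0 items past the adjusted threshold and 679 meeting the design-text rule.

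**Figure D4:**
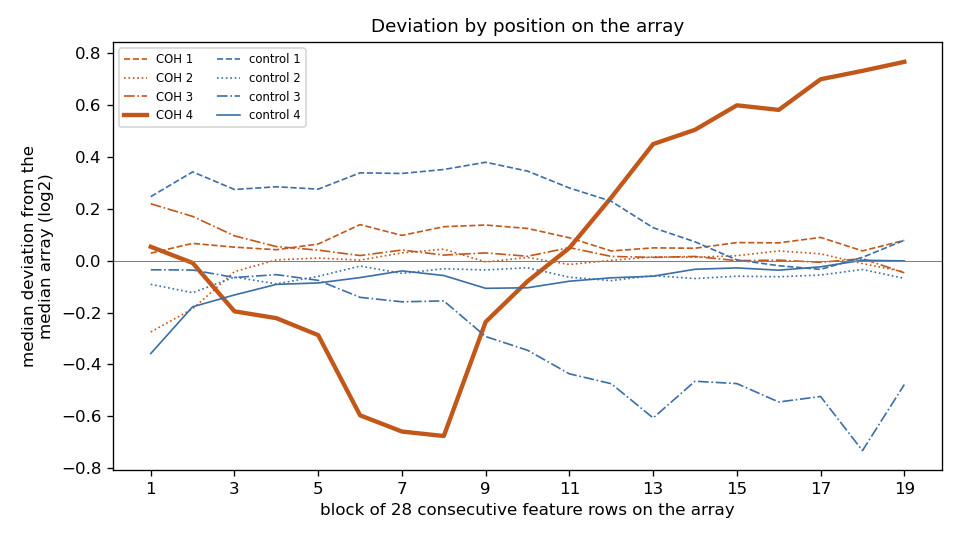
Median log2 deviation of each array from the median array (vertical axis) over spots with distinct values, in 19 blocks of 28 consecutive feature rows (horizontal axis), control arrays in blue and COH arrays in orange. COH 4 (thick line) runs from -0.68 to 0.77, and control 3 has the next widest range, 0.70.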

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

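The test of whether spots near background fill the gene selection, and the tests of position and of weak signal on the COH 4 array, were chosen after those results had been seen; the splits of the samples and the test of repeated spots were set before. Outlying samples were looked for in 132 groups of 4 (array measures, named genes and list means), and 12 had a sample far from the other 3, where chance marks about 1 in 20.

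The array of COH replicate 4 stood apart in the range of its deviation between position blocks (1.44; the other COH arrays 0.11 to 0.32). A trend over the array as the whole reason is argued against by its mean correlation with the other arrays, which stayed lowest after the trend was removed, at 0.752 against 0.801 or more. The trend remains a candidate explanation for part of the disagreement of repeated spots. Their median SD on COH 4 went from 0.78 to 0.452 with the trend removed. That is below the highest other array, COH 2 (0.454), but above the 0.309 to 0.360 of the remaining arrays. Weak signal did not show in the measures at hand. COH 4 had the most spots with a value (42076), and 53.1% of its values were shared, inside the range of the others. The authors' quality criteria set which spots carry a value, and intensities were not used, so weak signal is not excluded. A biological property of this pool stays open, since the pool was measured on 1 array.

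The 880 items meeting the design-text rule could be a matter of how the arrays were grouped. Of the 8 splits that part all 4 pairs, 4 gave as many items, the real one included, and the highest other split gave 1287. With 8 splits a share under 0.05 cannot be reached. For the 0 items past the adjusted threshold (8 of 8 splits as large, highest other 0) and the 0 lists (8 of 8, highest other 1) the comparison decides nothing. Every split gives a count of at least 0. Without the block 29 of the 35 splits gave as many as the real 697 (highest other 1923, with 7 items past the adjusted threshold, for control 1, COH 1, COH 3 and COH 4 against the rest), so chance is not excluded. Noise of spots near background may bear on which items were selected, as 24.8% had a spot with distinct values, against 45.5% of the others.

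Among named genes, COH 4 had the lowest value of its group for Cx3cr1 (-0.63; the others 1.12 to 1.45), Slc23a1 (-3.02; -1.82 to -1.65) and Glul (0.27; 0.76 to 0.84). Control 3 was lowest for Glul (-1.60; 0.21 to 0.50) and control 4 for Slc23a1 (-1.61; -0.23 to 0.04). Control 2 was highest for Ackr3 (-2.11; -3.21 to -3.13) and control 1 for Derl3 (3.66; 0.92 to 1.15). Control 3 had the highest array median (0.125; -0.01 to 0.00) and the lowest mean of neurotrophic factors and receptors (-0.71; -0.12 to -0.04). Control 1 had the highest mean of the glycolysis list (-0.23; -0.56 to -0.51) and COH 2 the lowest mean of amacrine and horizontal cell markers (-0.25; 0.11 to 0.18).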

How the results depend on the processing

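Alternatives on distinct values, array position, the COH 4 array and genes with at least 5 spots were chosen after seeing the data; the others were set before. No alternative gave an item or a gene list with an adjusted p under 0.05. At 0.10, looked at for items in the main comparison only, there was no item; among lists, ribosomal proteins lay under it with distinct values only (0.0828) and with the position trend also removed (0.0950). The count meeting the design-text rule, 880, moved by over 1.5 times in 5 settings. It was 566 with a plain test of the 4 within-pair ratios (400 shared with the 880) and 541 with no block and COH 4 left out. With distinct values only it was 431 of 8278 items tested, and 264 of them with the position trend also removed. Those 8278 items held 218 of the 880, and 205 of the 218 were among the 431. The share of tested items was 4.73% in the main comparison, 5.21% with distinct values only and 3.19% with the trend also removed. Among 188 genes with at least 5 spots, 1 of them in the 880, the count was 3. Fewer items were tested with distinct values and with at least 5 spots, so those counts do not compare directly with 880. What else moved the counts was not tested. With no replicate block, the pairing ignored, the count was 697, 559 of them shared with the 880. The number of items past the adjusted threshold was 0 with and without the block. Leaving out 1 pair gave 679 to 1079. The share of higher items was 54.2%, but 83.1% with distinct values and 33.9% with the position trend removed, which moved the median difference of all items from 0.08 to -0.04, so the split has no stable direction.

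Of the 28 named genes, only markers with differences under 0.4 reversed under an alternative. The 20 named by p were chosen for 4 of 4 pairs in the same direction, so leaving out a pair could not reverse them, and several settings leave a difference as it is by construction. Gap43 reversed with array weights (-0.027), with the position trend removed (-0.056), with distinct values too (-0.11), and with no block and no COH 4 (-0.046). With the position trend removed Nefl was -0.15 and Gfap -0.086. Leaving out 1 pair gave ranges of -0.24 to 0.12 for Nefm, -0.19 to 0.080 for Sncg, -0.16 to 0.39 for Nefl, -0.12 to 1.27 for Aif1, -0.13 to 0.41 for Gap43 and -0.080 to 0.45 for Gfap. The cause was not tested. Signal over background is unknown here, so what it limits could be judged only from shared values.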

Other observations

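The test on olfactory receptors with distinct spots was chosen after the result had been seen, and the test on genes of other tissues was set before its own result but after the olfactory pattern and the levels of taste and vomeronasal receptors had been seen. Olfactory receptors, the odorant receptors of the nasal epithelium, lay above the reference RNA more often than named genes as a whole. The 372 measured had a median log2 ratio of 1.87 in control cells, and 297 (79.8%) were above the reference on all 4 control arrays, against 22.3% of all named genes. Of the 50 genes highest on their lowest array among 4985 with distinct spots, 20 were olfactory receptors, which made up 1.85% of the genes ranked (Fisher's exact test, two-sided, p = 7.29e-23, chosen after the values were seen). Since the test was prompted by these same values, its p adds no support beyond the counts. Or6c214b led with 3.26 ± 0.43 (SD, n = 8 arrays). At the other end were Tfrc, the transferrin receptor, at -4.62 ± 0.51, and Nr3c1, the glucocorticoid receptor, at -4.46 ± 0.59. The mitotic kinase Bub1 was at -3.99 ± 0.40.

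That olfactory receptors lie above the reference only because their spots share values is argued against: 90.2% of the 92 with a distinct spot were above the reference on 8 of 8 arrays, against 12.4% of the other named genes with such spots. Faint signal as such is not excluded by this. Over all named genes, the median control level was -0.407 for genes without a distinct spot and -0.419 for genes with one. A gene without a distinct spot may share its value on a single array only. These medians therefore do not decide whether faint signal raises a ratio. A candidate explanation is that genes made by neither RNA give a ratio above 0. A list of 78 genes of pancreas, testis, muscle, milk and other tissues, 32 of them measured, had a median control level of 1.16, which is 1.58 above that of all named genes and above the median of every one of 10000 random lists of its size (permutation p = 1e-04, the smallest they can give). Its members ranged from -1.76 ± 0.93 (Csn1s1) to 2.47 ± 1.34 (Tdo2; SD, n = 4), 17 of 32 were above the reference on all 4 control arrays and 9 had a mean below 0. The 7 with a distinct spot had a median of 0.60 and the rest one of 1.24. The random lists were drawn from all named genes, of which 50.9% had a distinct spot, and were not matched for this. Genes share the same 4 control arrays, so the permutation p does not measure a spread between pools. Whether either RNA holds these transcripts was not tested. Given the level of this list, a ratio above 0 may not show expression in RGCs. That limit covers photoreceptor and bipolar cell markers. It also covers the lists of RGC markers (median 0.35), synaptic genes (0.60) and receptor genes (0.78), which all lay below 1.16. Expression of olfactory receptors in these cells was not tested by other means.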
